A study of Homo sapiens with 9 samples.

How the data were processed

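Total RNA was sequenced from 9 cultures of neural crest-like cells derived from H9, an established human embryonic stem cell line. Per the labels' protocols, H9 clumps were differentiated for 6 days in a chemically defined medium with 10 µM SB431542, a small-molecule inhibitor of the receptors for Nodal, Activin and TGF-β. Cells with high CD271 and no CD73 were then sorted and expanded on fibronectin under 5% oxygen. The cell type label of the same samples instead gives both markers as positive, so the sort is described here as the growth protocol gives it. Expansion was in the same base medium with 5 to 10 ng/ml FGF2 alone (group F), or with FGF2 and 3 to 5 µM SB431542 (group FSB). In group F_FSB, cells expanded in FSB for 4 passages were moved to F for 3 more. All cultures were harvested at passage 6 to 7, and the design text calls the 3 samples of each group biological replicates. Libraries were made with a strand-specific SureSelect kit. Whether the quantification used the strand is not given in the sources used here, so antisense and overlapping genes are uncertain.

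The deposited values are FPKM (fragments normalized to transcript length and to the library's mapped fragments) from Cufflinks gene tables, per the file headers. The submitters' processing notes name TopHat2 2.0.12, Cufflinks 2.1.1 and the genome build GRCh37. Each library has its own table of 25593 loci, listed by gene symbol, and none of the loci is mitochondrial. Cufflinks normalized each library to its own fragments, and options, masking and filters are not given in the sources used here. FPKM sums ran from 361026 to 506146 per library. The highest sum, in F_FSB replicate 2, included 111389 FPKM for the microRNA gene MIR4461. Deposited FPKM of very short genes lay far above the interval that Cufflinks gave in the same table, so microRNA and small nucleolar RNA genes are not named as results. No pair of libraries held identical tables. The largest share of equal nonzero values between any pair was 0.00525%.

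The tables hold no fragment counts, so the depth is known only in relative terms. In each library, the commonest low value of intronless olfactory receptor genes, times gene length, was assumed to be that of a single fragment. From 2 to 8 such genes per library, the relative depth was 82.7% to 100% of the deepest library in 8 libraries and 60.0% in F_FSB replicate 2. These are rough estimates. The shallower library gives less precise values for low genes.

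Starts in the tables count from 0, and coordinates are given here 1-based on GRCh37. Genes with a quantification status other than OK in any library (95 loci) were left out. Genes with an FPKM of 1 or more in at least 3 libraries were tested, which left 13216 genes. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 9 libraries in 1 fit of group means. Tests were two-sided, with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. Log2 changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were FSB minus F, F_FSB minus FSB and F_FSB minus F. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used to join the tables and draw the figures.

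Gene lists for crest and mesenchymal identities, signalling responses, metabolism and other cell types were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with BH adjustment over lists and comparisons. Camera with an estimated correlation and limma's fry were run beside it. Mitochondrially encoded genes could not be assessed because the tables hold no such loci. Named genes followed a rule fixed before the data were examined. It took the 10 largest increases and the 10 largest decreases per comparison among genes past the threshold, with a mean of 5 FPKM or more in the higher group and no overlap between the groups' libraries. It left out symbols beginning with LOC, MIR, SNOR, LINC, RPL, RPS or MT-, symbols with a dot and repeated symbols. It added 2 to 4 members of each list with the smallest adjusted p, and SOX9, NGFR (CD271) and NT5E (CD73). Other genes named in the text are identified as chosen after their values were seen. Some genes that the rule takes are not reported here.

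The test was run on simulated data with 200 changed genes among 13216 and the spread of each group, in 20 draws. For FSB minus F it recovered 73.5% of genes changed by 1 on the log2 scale and 92.0% of those changed by 2, with 3.25% false calls. For F_FSB minus FSB it recovered 73.3% and 91.0%, with 6.47% false calls. For F_FSB minus F it recovered 71.2% and 90.5%, with 10.1% false calls, above the 5% aimed at. The BH cutoff depends on how many genes change. In the real data 5536, 5527 and 1 genes passed in these comparisons, so the simulated rates may not apply to them. The root mean square of deviations from the group mean, on the log2 scale, was 0.388 in F, 0.300 in FSB and 0.463 in F_FSB.

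The overlap of opposite changes between FSB minus F and F_FSB minus FSB was compared with 100 simulations of unchanged groups that share the FSB libraries. Alternatives covered the pseudocount, the filter on low values, scaling, the mean-variance trend, the libraries in the fit, library weights, a minimum change, the culture number as a block and each library left out in turn. Leaving out short genes, whose mean FPKM was over 1.5 times the middle of the Cufflinks interval, was chosen after seeing the data. Transcript lengths from GENCODE annotation on GRCh37 were found for 84.4% of tested genes other than small RNAs (11035 of 13082) and were used to turn FPKM into shares of fragments.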

Results

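Gene expression was measured by RNA sequencing in 9 cultures of neural crest-like cells derived from the human embryonic stem cell line H9, 3 in each of 3 media. Cells in F were expanded with the growth factor FGF2. Cells in FSB received FGF2 with SB431542, which blocks the receptors for Nodal, Activin and TGF-β. Cells in F_FSB were expanded in FSB for 4 passages and then kept in F for 3 more. All cells had received SB431542 during differentiation, so F is the group from which it was removed before expansion. No cells from the start of expansion were among the 9 libraries. Words such as rose and fell therefore compare groups and do not describe change from the starting cells. The values are FPKM as the authors deposited them. Fragment counts are not in the tables. The relative depth, a rough estimate, was 60.0% of the deepest library in F_FSB replicate 2 and 82.7% to 100% in the others.

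The FSB libraries stood apart from all the others. On the leading principal component of log2(FPKM + 1), which held 52.9% of the variance, FSB libraries lay between 59.5 and 61.7 and the other 6 between -35.4 and -18.3. Pearson correlations across genes, which are not independent replicates, were 0.964 to 0.983 among FSB libraries, 0.943 to 0.959 among F libraries and 0.916 to 0.947 among F_FSB libraries. Between groups they were 0.854 to 0.875 for F with FSB, 0.837 to 0.887 for F_FSB with FSB and 0.908 to 0.967 for F with F_FSB. F replicate 1 had 0.944 and 0.943 with F replicates 2 and 3, and 0.967, 0.929 and 0.953 with F_FSB replicates 1, 2 and 3. On the next principal component, with 14.3% of the variance, it lay at 4.25. F replicates 2 and 3 lay there at -27.7 and -31.4, and F_FSB libraries between -9.12 and 48.6.

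The genes used to name and sort the cells behaved differently from each other. SOX9 (chromosome 17, 70117161 to 70122561), a transcription factor of crest and cartilage cells, had means of 32.5 ± 22.7 FPKM in F, 34.15 ± 10.9 in FSB and 19.5 ± 7.76 in F_FSB (SD, n = 3), and passed the test in none of the 3 comparisons (limma, BH-adjusted p = 0.742 for FSB minus F, 0.226 for F_FSB minus FSB and 0.709 for F_FSB minus F). NGFR (chromosome 17, 47572655 to 47592382), which encodes the sort marker CD271, was at 20.0 ± 20.4 FPKM in F, 120 ± 15.3 in FSB and 4.89 ± 3.01 in F_FSB. It was higher in FSB than in F (log2 change 3.44, SE 1.05, limma with BH adjustment, adjusted p = 0.0306) and fell by 4.53 on withdrawal (limma, BH-adjusted p = 0.00983). The F libraries were uneven, at 0.725, 41.3 and 18.0 FPKM. The higher call in FSB was lost without FSB replicate 1, 2 or 3 (limma, BH-adjusted p = 0.0824, 0.0797 and 0.0646, with log2 changes of 3.36, 3.41 and 3.54). NT5E (chromosome 6, 86159302 to 86205509), which encodes CD73, was at 72.9 ± 22.9 FPKM in F, 20.0 ± 9.37 in FSB and 63.0 ± 15.0 in F_FSB. It was lower by 1.90 in FSB than in F and higher by 1.71 in F_FSB than in FSB (limma, BH-adjusted p = 0.00667 and 0.00994).

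**Figure D1:**
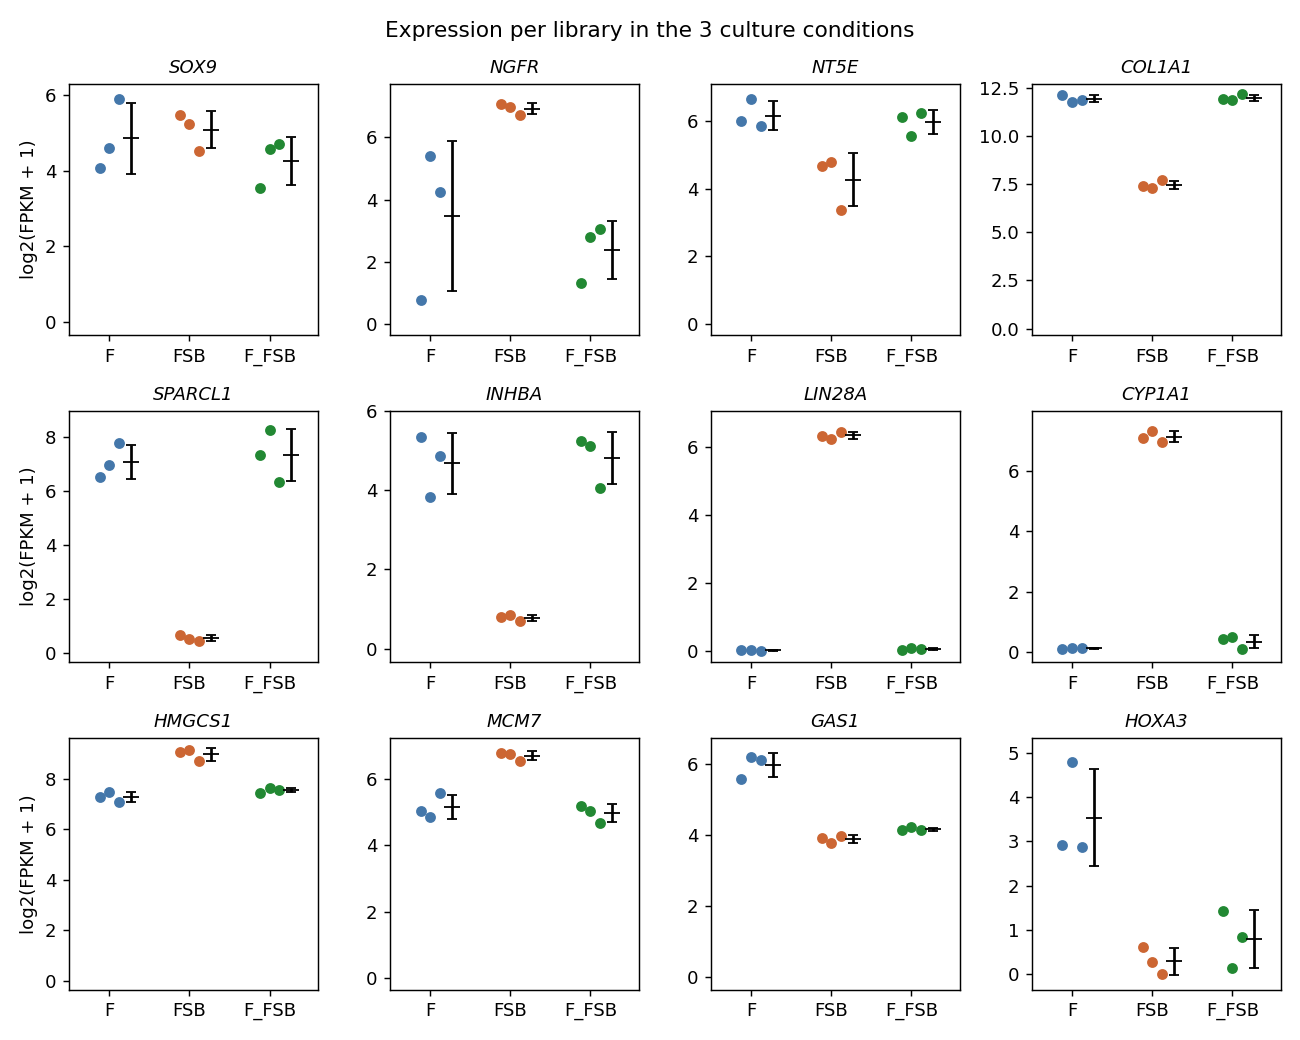
Log2(FPKM + 1) of 12 genes in each of the 9 libraries (vertical axes, each on its own scale) by culture medium (horizontal axes); points are libraries and black bars are the mean and SD of 3. LIN28A and CYP1A1 are near 0 in F and F_FSB and above 6 in FSB, COL1A1 is lower in FSB, and GAS1 and HOXA3 in F_FSB lie near FSB.

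The comparison of FSB with F asks how expanded cells differ when Nodal, Activin and TGF-β receptor signalling stays blocked after differentiation. Among genes taken by the naming rule, the largest increase with the inhibitor was that of CYP1A1 (chromosome 15, 75011883 to 75017877), a cytochrome P450 that oxidizes aromatic compounds, from 0.0876 ± 0.0173 FPKM in F to 141 ± 18.6 in FSB (SD, n = 3; log2 change 7.02, SE 0.13, limma with BH adjustment, adjusted p = 7.67e-08). It was followed by LIN28A (chromosome 1, 26737269 to 26756219), an RNA-binding protein that blocks let-7 microRNA maturation, from 0.0110 ± 0.00982 to 79.5 ± 5.55 FPKM (log2 change 6.31, limma, BH-adjusted p = 9.0e-09). Its paralog LIN28B went from 1.70 ± 2.25 to 60.5 ± 8.32 FPKM. TAC1, a neuropeptide precursor, IGDCC3, MASP1, ANKRD1, RARRES2 and the efflux transporter ABCG2 were also among the leading genes, with log2 changes from 6.09 to 4.79. The largest decreases were those of the joint lubricant gene PRG4 (chromosome 1, 186265405 to 186283688), from 119 ± 74.8 to 0.0242 ± 0.0164 FPKM, and of the matrix protein gene SPARCL1 (chromosome 4, 88394487 to 88450655), from 144 ± 65.4 to 0.469 ± 0.118 FPKM (log2 changes -6.55 and -6.53, limma, BH-adjusted p = 0.00353 and 9.79e-05). EMP1, MFAP4, DLK1, POSTN, ISLR, DCN, NFIX and LTBP2 followed, with log2 changes from -6.47 to -5.29.

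Of 13216 genes tested, 5536 (41.9%) passed the threshold between FSB and F, 3763 higher and 1773 lower in FSB (limma with BH adjustment). By at least 1 on the log2 scale, 822 were higher and 711 lower. The libraries of the groups did not overlap for 57.9% of genes, against 10% by chance with 3 against 3 libraries. The split by direction depended on scaling. The median change of all genes was 0.14 on the log2 scale with the deposited values, and 68.0% of calls were higher in FSB. Scaling by median ratios gave 2413 higher and 2463 lower (49.5% higher), quantile normalization gave 2636 and 2316 (53.2%), and scaling to the same sum gave 2424 and 1584 (60.5%). List medians and means below are given relative to the median of all genes.

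Matrix genes were lower in FSB. Of 30 fibrillar matrix genes, 20 fell, 0 rose and 10 did not pass (22 lower when adjusted over the list alone), with a median of -1.33 relative to all genes. COL1A1 (chromosome 17, 48261457 to 48279000), the main chain of type I collagen, went from 3941 ± 505 FPKM in F to 176 ± 26.9 in FSB (SD, n = 3; log2 change -4.48, SE 0.19, limma, BH-adjusted p = 9.57e-06). DCN, a small proteoglycan, went from 170 ± 87.0 to 2.37 ± 0.902 FPKM, COL6A1 from 1247 ± 442 to 228 ± 27.5 and COL6A2 from 1499 ± 303 to 320 ± 57.3. COL3A1, chosen after its values were seen, had 1183 ± 123 FPKM in F and 1276 ± 387 in FSB and did not pass. The list passed camera (BH-adjusted p = 1.54e-09), with adjusted p = 0.127 with an estimated correlation. By length-weighted FPKM, these 30 genes took an estimated 8.73% ± 0.454 of fragments in F, 2.87% ± 0.161 in FSB and 8.78% ± 0.431 in F_FSB (SD, n = 3).

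Of 14 surface genes of mesenchymal stromal cells, 8 fell, 1 rose and 5 did not pass, the same counts when adjusted over the list alone (median -1.50 relative to all genes; camera, BH-adjusted p = 0.00896, and adjusted p = 0.232 with an estimated correlation). CSPG4, ANPEP and VCAM1 fell by 2.19, 3.09 and 2.88, and MCAM, an adhesion molecule of perivascular cells, rose from 26.1 ± 19.4 to 148 ± 28.4 FPKM. Without F replicate 2, 2 stromal genes rose. Of 19 genes of the TGF-β and activin response, 7 fell, 4 rose and 8 did not pass, also when adjusted over the list alone (median -0.60 relative to all genes; camera, BH-adjusted p = 0.0221, and adjusted p = 0.817 with an estimated correlation). LTBP2, JUNB and INHBA, which encodes the activin A subunit, fell by 5.29, 2.15 and 3.91. The members that rose were COL4A1 and COL4A2, which encode basement membrane collagen, TGFB1, a ligand of the pathway, and LMCD1, a transcriptional cofactor chosen after its values were seen. Without F replicate 2, or without FSB replicate 1, 2 or 3, 2 members rose. COL4A1 went from 196 ± 59.1 to 491 ± 25.4 FPKM (log2 change 1.36, limma, BH-adjusted p = 0.00341). SMAD7, a textbook target chosen after its values were seen, had 9.29 FPKM in F and 6.09 in FSB and did not pass (limma, BH-adjusted p = 0.233).

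Cell cycle and sterol genes were higher in FSB. Of 21 proliferation genes 20 rose and 1 did not pass, also over the list alone (median 0.94 relative to all genes; camera, BH-adjusted p = 8.56e-05, and adjusted p = 0.655 with an estimated correlation). The replication helicase subunit MCM7 went from 35.5 ± 9.91 to 103 ± 9.19 FPKM and TYMS from 57.4 ± 11.2 to 129 ± 11.7. Of 16 cholesterol synthesis genes 15 rose and 1 did not pass, also over the list alone (median 1.02 relative to all genes; camera, BH-adjusted p = 2.26e-05, and adjusted p = 0.640 with an estimated correlation). HMGCS1, an enzyme of the pathway, went from 155 ± 21.1 to 500 ± 80.5 FPKM (limma, BH-adjusted p = 0.000233). No member of either list turned to lower calls with any of the 3 scaling alternatives. Between 17 and 18 proliferation genes and between 13 and 14 cholesterol genes were higher there.

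Of 16 contractile genes 8 rose, 1 fell and 7 did not pass (9 and 2 over the list alone; median 0.49 relative to all genes; camera, BH-adjusted p = 0.0556, and adjusted p = 0.655 with an estimated correlation). The actin-binding genes TAGLN and CNN1 went from 191 ± 51.6 to 717 ± 226 FPKM and from 7.34 ± 1.73 to 32.7 ± 6.56, and LMOD1 from 0.850 ± 0.503 to 44.8 ± 25.2. ACTA2, smooth muscle actin, had 34.4 ± 13.2 FPKM in F and 45.3 ± 12.7 in FSB and did not pass. Without F replicate 1, 11 contractile genes rose and 2 fell. Of 6 pluripotent cell markers tested, 4 rose and 2 did not pass (5 higher over the list alone; camera, BH-adjusted p = 0.0135, and adjusted p = 0.615 with an estimated correlation). Besides LIN28A, SALL4 went from 0.244 ± 0.177 to 16.1 ± 1.01 FPKM and DNMT3B from 2.84 ± 0.923 to 6.73 ± 0.961. The core pluripotency factors POU5F1, NANOG and SOX2, chosen after their values were seen, were too low to be tested, with FSB means of 0.0649, 0.0171 and 0.168 FPKM.

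Crest and skeletal identity genes moved in both directions. Of 15 neural crest genes 5 rose, 2 fell and 8 did not pass, also over the list alone (camera, BH-adjusted p = 0.754, and adjusted p = 0.859 with an estimated correlation). ETS1, SOX8 and TFAP2A, transcription factors of the crest, rose by 1.89, 2.46 and 2.00, and MSX2 fell by 3.71. Without FSB replicate 1, 2 or 3, 3 rose, and without FSB replicate 2, 1 fell. SOX10, chosen after its values were seen, was too low to be tested, at 0.0178 FPKM in F, 0.612 in FSB and 0.00571 in F_FSB. Of 21 ectomesenchyme genes 5 rose, 6 fell and 10 did not pass (5 and 7 over the list alone; camera, BH-adjusted p = 0.476, and adjusted p = 0.831 with an estimated correlation). The median of that list was 0.0039 and its mean -0.47, with camera's direction down. TWIST1 went from 28.7 ± 7.26 to 96.0 ± 3.62 FPKM, while OSR1 fell by 3.70. Of 39 HOX genes quantified, which mark position along the body axis, 3 passed the filter on low values. All 3 were lower in FSB, also over the list alone. HOXA3 (chromosome 7, 27145809 to 27166639), HOXB2 and HOXA2 fell by 3.24, 1.85 and 2.55 (limma, BH-adjusted p = 0.00254, 0.00261 and 0.00919). HOXA3 and HOXB2 would not have passed the filter without the F libraries. The filter thus favoured lower values in FSB, and these counts do not describe HOX genes as a whole.

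Of 11 chondrogenic genes 2 rose, 3 fell and 6 did not pass (4 and 3 over the list alone; camera, BH-adjusted p = 0.791, and adjusted p = 0.923 with an estimated correlation). COL2A1, the collagen of cartilage, went from 1.45 ± 0.539 to 50.3 ± 4.63 FPKM (log2 change 4.41, SE 0.46, limma, BH-adjusted p = 0.000402) and FGFR3 from 0.347 ± 0.177 to 1.59 ± 0.129, while MATN3 went from 3.91 ± 1.68 to 1.15 ± 0.361. Without FSB replicate 1, 2 or 3, 1 fell, and without F replicate 1, 4 rose. Camera's direction and the mean of -0.12 were down, and the median was 0.09. Of 5 osteogenic genes 1 rose, 1 fell and 3 did not pass, also over the list alone (camera, BH-adjusted p = 0.435). Without F replicate 1 or 3 or FSB replicate 1, 2 or 3, 0 rose and 0 fell. Without F_FSB replicate 1, 0 rose, and without F_FSB replicate 2, 0 fell. RUNX2, a regulator of bone formation, had 4.12 ± 2.24 FPKM in F and 1.64 ± 0.513 in FSB and did not pass. Of the 2 adipogenic genes tested, lipoprotein lipase (LPL) rose from 0.0605 ± 0.0937 to 20.8 ± 1.51 FPKM and PPARG fell by 1.74.

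Of 12 BMP response genes 2 rose and 3 fell (camera, BH-adjusted p = 0.651), and ID3 rose by 0.88. Without F replicate 1 or FSB replicate 1 or 2, 1 rose and 2 fell. The BMP list's median was 0.09 and its mean -0.46, with camera's direction down. Of 16 FGF and ERK response genes 2 fell and 14 did not pass (0 and 0 over the list alone; camera, BH-adjusted p = 0.165), and of 6 WNT response genes 1 rose and 5 did not pass (camera, BH-adjusted p = 0.757). Higher and lower FGF and ERK genes numbered 0 and 4 without F replicate 1, 1 and 2 without F replicate 3, 0 and 1 without FSB replicate 1 and 1 and 1 without FSB replicate 3. WNT genes gave 1 and 1 without F replicate 3 or F_FSB replicate 3, and 0 and 0 without FSB replicate 1. Of 14 hypoxia and glycolysis genes 4 rose and 1 fell (camera, BH-adjusted p = 0.887). VEGFA went from 26.6 ± 4.53 to 11.7 ± 0.775 FPKM and HK2, hexokinase, rose by 1.33. The hypoxia list's median was 0.32 and its mean 0.05, with camera's direction down. Without F replicate 3, 3 rose and 2 fell. Of 11 stress response genes 5 rose and 6 did not pass (5 higher and 2 lower over the list alone; camera, BH-adjusted p = 0.887). ASNS, asparagine synthetase, went from 5.33 ± 0.805 to 32.0 ± 15.3 FPKM and ATF3 from 2.33 ± 0.764 to 6.12 ± 0.618. Without F replicate 1 or 2, FSB replicate 1 or 2 or F_FSB replicate 1, 3 stress genes rose. Without F replicate 2 or 3, 1 fell. With scaling by median ratios, the stress list had 3 higher and 2 lower and the hypoxia list 2 and 2, and quantile normalization gave 3 and 2 for each.

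None of 5 peripheral neuron markers passed (limma; camera, BH-adjusted p = 0.764), and neither of the 2 paraxial mesoderm markers did. Without F replicate 1 or FSB replicate 3, 2 neuron markers rose, and without F replicate 1, 1 paraxial marker fell. NES, the tested marker of central neuroectoderm, went from 60.2 ± 29.1 to 227 ± 33.5 FPKM. Of 5 endothelial markers 2 rose and 2 fell (2 and 3 over the list alone; camera, BH-adjusted p = 0.726). CDH5 went from 0.143 ± 0.0822 to 3.43 ± 0.451 FPKM and TEK from 3.40 ± 1.26 to 0.131 ± 0.125. Of 5 epithelial markers 2 rose (camera, BH-adjusted p = 0.754), with CLDN6 at 0.143 ± 0.0567 FPKM in F and 2.88 ± 1.32 in FSB. Without F replicate 2 or 3 or FSB replicate 1 or 2, 1 epithelial marker rose. Of 4 Schwann and glial markers 1 rose and 1 fell, PMP22 from 63.9 ± 8.84 to 23.2 ± 1.59 FPKM. Leaving out any 1 of the F or FSB libraries gave 0 higher Schwann and glial markers. Of 3 melanocyte markers 2 rose, but 0 without F replicate 3 and 1 without F replicate 1 or 2 or FSB replicate 1 or 2. None of the endoderm markers passed the filter, and their highest group mean was 1.55 FPKM.

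**Figure D2:**
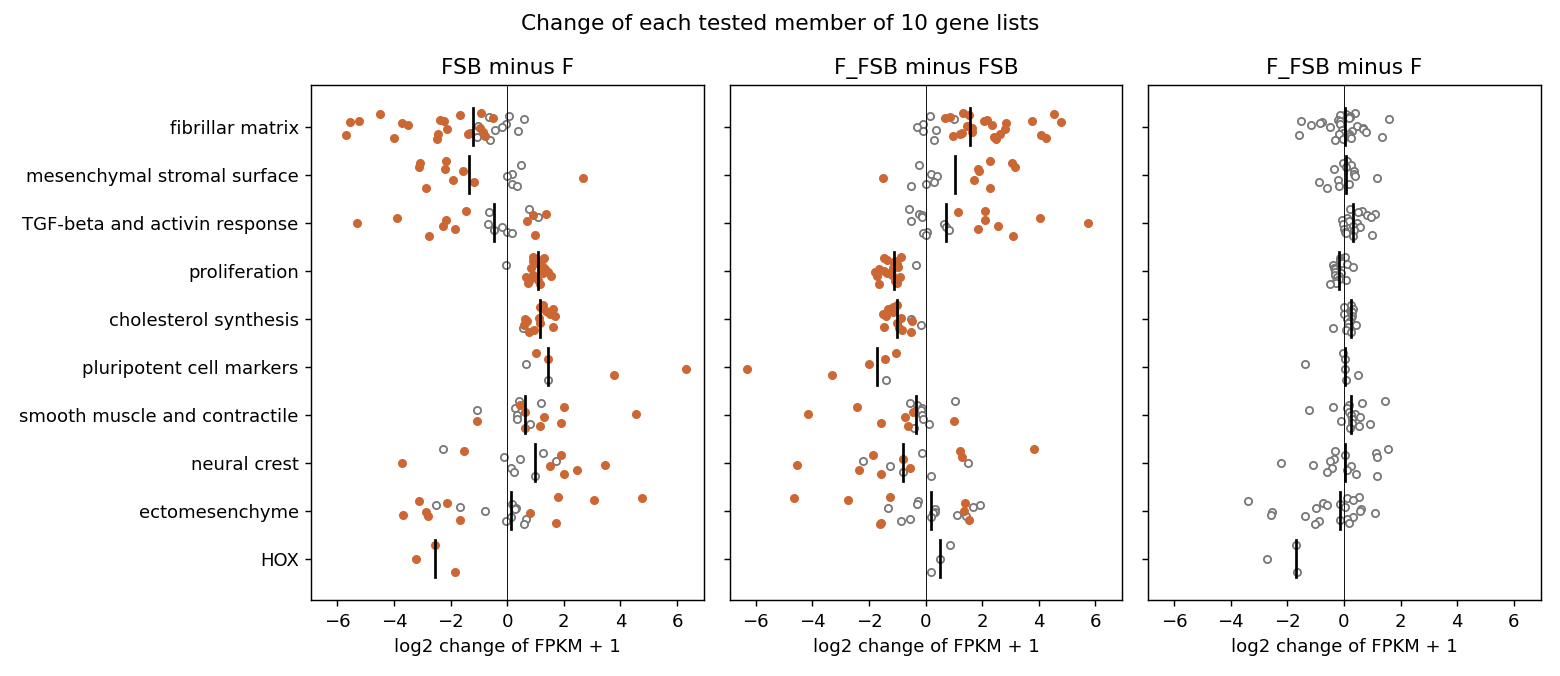
Log2 change of FPKM + 1 (horizontal axes) for each tested member of 10 gene lists (vertical axis) in the 3 comparisons; filled points passed the test at an adjusted p of 0.05, open points did not, and black bars are list medians, not relative to all genes. Matrix and stromal genes lie mostly left of 0 in FSB minus F and right of 0 in F_FSB minus FSB, proliferation and cholesterol genes the other way, and no point is filled in F_FSB minus F.

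The comparison of F_FSB with FSB follows cells after withdrawal of the inhibitor. SPARCL1 rose by 6.77 on the log2 scale, from 0.469 ± 0.118 FPKM in FSB to 184 ± 116 in F_FSB (SD, n = 3; SE 0.47, limma with BH adjustment, adjusted p = 0.000101). EMP1, LTBP2, the secreted protease HTRA1, the water channel AQP1, SCG2, the growth factor HGF, MFAP4 and NTN4 were also among the leading genes, with log2 changes from 5.79 to 4.91. The largest decreases among named genes were those of CYP1A1, from 141 ± 18.6 to 0.275 ± 0.175 FPKM, and LIN28A, from 79.5 ± 5.55 to 0.0301 ± 0.0204 (log2 changes -6.80 and -6.29, limma, BH-adjusted p = 9.94e-08 and 9.32e-09). TAC1, at 82.5 ± 41.4 FPKM in FSB, was listed at 0 in all 3 F_FSB libraries. MASP1, IGDCC3, ABCG2, A2M, NGFR and TRIM71, a stem cell RNA-binding protein, were also among the leading decreases, with log2 changes from -5.16 to -4.37.

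Between F_FSB and FSB, 5527 genes (41.8%) passed, 1805 higher and 3722 lower after withdrawal (limma with BH adjustment), and 704 and 806 by at least 1 on the log2 scale. The median change of all genes was -0.13. Of the calls, 32.7% were higher with the deposited values, 49.9% with scaling by median ratios (2510 higher and 2525 lower), 45.7% with quantile normalization (2318 and 2756) and 26.8% with scaling to the same sum (1306 and 3565). The sum of F_FSB replicate 2 included 111389 FPKM for the microRNA gene MIR4461, so scaling to the same sum lowered the other genes of that library. The libraries of the groups did not overlap for 55.8% of genes, against 10% by chance.

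Matrix genes rose on withdrawal. Of 30 fibrillar matrix genes 23 rose and 7 did not pass (24 over the list alone; median 1.71 relative to all genes; camera, BH-adjusted p = 2.5e-10, and adjusted p = 0.127 with an estimated correlation). COL1A1 was at 4102 ± 471 FPKM in F_FSB, and DCN rose by 4.79. Of 14 stromal surface genes 7 rose and 1 fell, also over the list alone (camera, BH-adjusted p = 0.00424, and adjusted p = 0.212 with an estimated correlation), with CSPG4, ANPEP, ENG and CD44 higher by 1.84, 3.06, 1.90 and 3.16. Without FSB replicate 1 or 2 or F_FSB replicate 3, 0 stromal genes fell. Of 19 TGF-β and activin response genes 8 rose, 0 fell and 11 did not pass (9 over the list alone; camera, BH-adjusted p = 0.000472, and adjusted p = 0.640 with an estimated correlation). INHBA went from 0.714 ± 0.0897 to 28.8 ± 11.6 FPKM and JUNB from 3.34 ± 0.511 to 17.7 ± 3.38. Without F replicate 1, 1 response gene fell. COL4A1, COL4A2 and TGFB1 did not pass, and COL4A1 had 422 ± 98.7 FPKM in F_FSB (limma, BH-adjusted p = 0.440 against FSB).

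Of 21 proliferation genes 20 fell (camera, BH-adjusted p = 1.29e-05, and adjusted p = 0.655 with an estimated correlation), MCM7 to 30.8 ± 5.49 FPKM and TYMS to 41.1 ± 9.14. Of 16 cholesterol synthesis genes 13 fell (camera, BH-adjusted p = 0.000243, and adjusted p = 0.655 with an estimated correlation), and 10 or 11 fell with scaling by median ratios or quantile normalization. Of 6 pluripotent cell markers 5 fell and 1 did not pass (6 over the list alone; camera, BH-adjusted p = 0.00799, and adjusted p = 0.563 with an estimated correlation). Of 16 contractile genes 6 fell and 1 rose (camera, BH-adjusted p = 0.416), with CNN1 at 5.64 ± 2.88 FPKM and TAGLN at 230 ± 19.9. Without F_FSB replicate 1, 2 contractile genes rose. Of 15 neural crest genes 3 rose and 6 fell (3 and 7 over the list alone; camera, BH-adjusted p = 0.764). ETS1, SOX8 and TFAP2A fell by 1.85, 2.36 and 1.57, and the integrin ITGA4 rose from 7.17 ± 1.26 to 19.1 ± 1.93 FPKM. Without FSB replicate 1 or 2 or F_FSB replicate 1, 1 rose. Of 21 ectomesenchyme genes 3 rose and 5 fell (camera, BH-adjusted p = 0.666), and 3 fell without FSB replicate 1 or 2 or F_FSB replicate 3. TWIST1 fell by 1.57. The ectomesenchyme list's median was 0.33 and its mean -0.04, with camera's direction up. Of 11 chondrogenic genes 1 rose and 3 fell (camera, BH-adjusted p = 0.841), with COL2A1 at 2.18 ± 2.42 FPKM in F_FSB. Without F replicate 2 or F_FSB replicate 1, 2 rose.

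On withdrawal 41.8% of all genes tested passed. For the remaining lists, counts of genes higher and lower were 1 and 1 of 5 for osteogenic, 2 and 2 of 12 for BMP, 1 and 1 of 16 for FGF and ERK, 0 and 1 of 6 for WNT, 3 and 3 of 14 for hypoxia and 1 and 3 of 11 for stress genes. Over the list alone the counts were 0 and 2 for BMP, 1 and 0 for FGF and ERK and 4 and 3 for hypoxia genes. Osteogenic genes gave 0 and 0 without FSB replicate 2 or 3, 0 and 1 without FSB replicate 1 or F_FSB replicate 3, and 1 and 0 without F_FSB replicate 2. BMP genes gave 0 and 1 without FSB replicate 1 or 2 or F_FSB replicate 1 or 2, and 1 and 2 without F replicate 1 or FSB replicate 3. FGF and ERK genes gave 1 and 2 without F replicate 3, 1 and 0 without FSB replicate 1 or 2 or F_FSB replicate 3, and 2 and 0 without F_FSB replicate 1. WNT genes gave 2 and 1 without F replicate 1 and 0 and 2 without F_FSB replicate 2. Stress genes gave 2 and 5 without F replicate 2 and 0 and 2 without FSB replicate 1. The camera tests of these lists gave BH-adjusted p from 0.499 to 0.930. Camera's direction was up for FGF and ERK genes, with a median of -0.07 and a mean of -0.01. None of the 3 HOX genes passed, with HOXA3 at 0.243 ± 0.261 FPKM in FSB and 0.858 ± 0.805 in F_FSB (SD, n = 3; limma, BH-adjusted p = 0.475). LPL fell by 3.39 and NES by 2.78. Of 5 endothelial markers 2 rose and 2 fell, of 5 epithelial markers 1 fell, of 4 Schwann and glial markers 1 rose, and of 3 melanocyte markers 1 fell. Without FSB replicate 2 or 3, 2 melanocyte markers fell, and without F replicate 1, 1 glial marker fell. None of the peripheral neuron or paraxial mesoderm markers passed, but 2 neuron markers rose without F_FSB replicate 3.

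Changes on withdrawal mirrored those with the inhibitor. Of the 5536 genes that passed between FSB and F, 5507 (99.5%) had the opposite sign in F_FSB minus FSB, against 94.2% of nominally changed genes in the simulations described next, 4456 (80.5%) passed in the opposite direction and 1 passed in the same direction. Both comparisons share the FSB libraries, which alone gives opposite signs. Unchanged groups sharing these libraries gave opposite signs for 66.6% of genes in 100 simulations, against 87.1% observed over all genes tested. They gave a mean correlation of log2 changes across genes of -0.50, against -0.88 observed, and a covariance of -0.051, against -0.578. The simulations gave each gene the same spread in all groups, although the FSB libraries varied least. Higher then lower calls numbered 3088, where independent lists would share 1060, and lower then higher calls numbered 1368, where independent lists would share 242. With 3 FSB libraries they could not be split, so part of the excess over both values may come from sharing. Among the 1533 genes that changed by at least 1 on the log2 scale between FSB and F, the median return was 92.0% of the change (quartiles 73.7% and 106%). Among the 1510 that did so on withdrawal, it was 106% (91.6% and 126%). Return here is the change on withdrawal, with its sign turned, as a percentage of the FSB minus F change. F_FSB cells had not been expanded in F before, so return measures nearness to the F level. Each set was chosen on its own comparison, which by itself can move the medians apart.

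**Figure D3:**
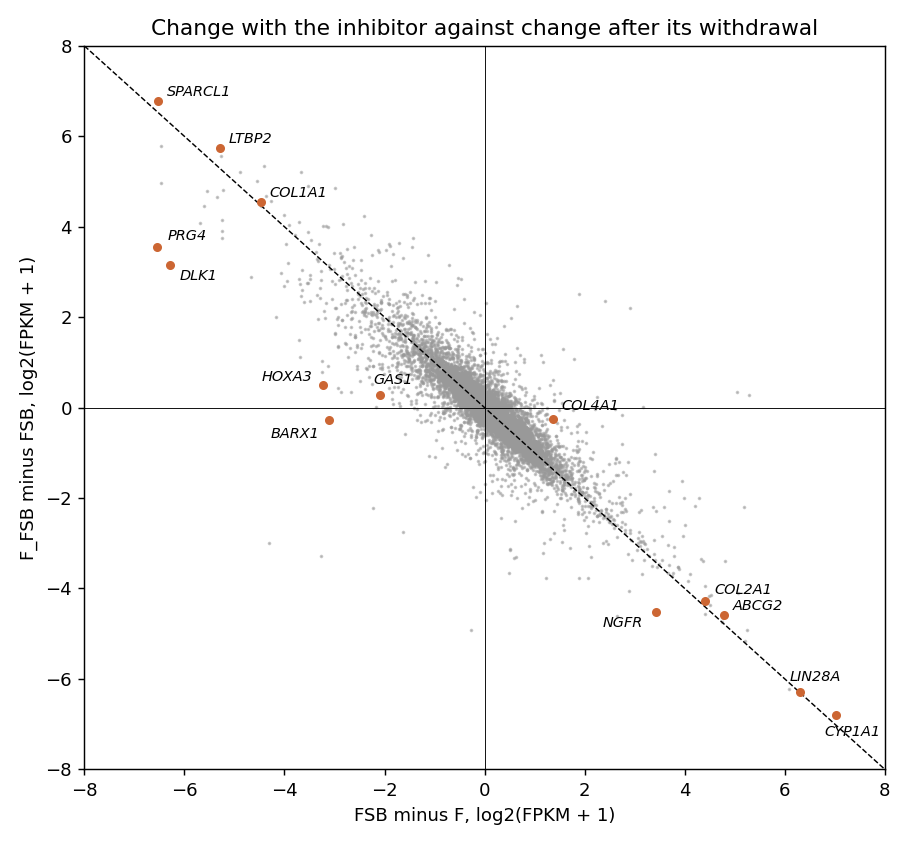
Log2 change of FPKM + 1 in FSB minus F (horizontal axis) against F_FSB minus FSB (vertical axis) for each of 13216 tested genes. The dashed line marks F_FSB equal to F, and orange points are named genes. Genes follow the line, with r = -0.88 against a mean of -0.50 in simulations of unchanged groups that share the FSB libraries. GAS1, HOXA3, BARX1 and COL4A1 lie near the horizontal line at 0.

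The comparison of F_FSB with F asks whether cells that end in the same medium differ when their earlier passages were with the inhibitor. All cells had it during differentiation, and F_FSB had only 3 passages without it, against the whole expansion in F. A lasting effect of those earlier passages and an incomplete change after 3 passages cannot be told apart. GAS1 (chromosome 9, 89559277 to 89562104), a membrane protein that binds Hedgehog ligands, was the single gene that passed, at 63.0 ± 13.9 FPKM in F and 17.0 ± 0.525 in F_FSB (SD, n = 3), near the 13.9 ± 1.09 of FSB. It fell by 1.80 on the log2 scale (SE 0.15, limma with BH adjustment, adjusted p = 0.0296), and every F_FSB library was below every F library. Its call was lost in 7 of the 9 fits that left out 1 library, with log2 changes between -1.83 and -1.73. These fits left out F replicate 3 (limma, BH-adjusted p = 0.246), FSB replicates 1 to 3 (0.147, 0.115 and 0.0664) and F_FSB replicates 1 to 3 (0.112, 0.105 and 0.0530). The call held without F replicate 1 or F replicate 2. It was also lost with the culture number as a block, without the filter on low values and in a fit of only the 2 groups compared. At an unadjusted p under 0.05, 1195 genes differed, where chance gives 660.8 if the groups have the same spread. The fit pooled 1 spread over the 3 groups, and the FSB libraries varied least. The pooled spread may thus be too small for this comparison. A fit of only the 2 groups compared gave 848 genes at that level (limma). The 95% confidence interval of the change lay within 1 on the log2 scale for 11275 genes (85.3%). That share was 69.8% for FSB minus F and 69.5% for F_FSB minus FSB, and the scale understates changes of low genes. The libraries of F_FSB and F did not overlap for 13.0% of genes, against 10% by chance. Leaving out F replicate 1 gave 77 genes (48 higher and 29 lower), leaving out F replicate 2 gave 4, leaving out F_FSB replicate 3 gave 2, and leaving out FSB replicate 3 or F_FSB replicate 1 gave 1 gene other than GAS1. Leaving out F replicate 3, FSB replicate 1, FSB replicate 2 or F_FSB replicate 2 gave 0, with 574, 974, 957 and 959 genes at an unadjusted p under 0.05 (limma). At that level there were 1873 genes without F replicate 1, 1037 without F replicate 2, 1463 without F_FSB replicate 3, 1182 without FSB replicate 3 and 1174 without F_FSB replicate 1.

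No member of any list passed over all genes in F_FSB minus F (limma). Adjusted over the list alone, all 3 HOX genes were lower in F_FSB, with HOXA3 at 13.2 ± 11.7 FPKM in F and 0.858 ± 0.805 in F_FSB and HOXB2 at 3.64 ± 2.27 and 0.358 ± 0.112 (SD, n = 3; limma, BH-adjusted p over all genes = 0.344 and 0.307). So were 3 ectomesenchyme genes, while 1 was higher. BARX1 had 22.3 ± 22.6 FPKM in F and 1.13 ± 1.95 in F_FSB, and LHX8 9.30 ± 9.05 and 0.427 ± 0.450, with wide spread in F, and the third was OSR1. MEIS2, the higher gene, had 31.1 ± 8.84 and 65.7 ± 2.39. HOXA3, HOXB2 and LHX8 would not have passed the filter on low values without the F libraries, which favours lower values in F_FSB. Over the list alone, 3 TGF-β and activin response genes, 1 contractile gene and 1 neural crest gene were higher in F_FSB. COL4A1 had 196 ± 59.1 FPKM in F and 422 ± 98.7 in F_FSB, and ITGA4 had 7.94 ± 1.63 and 19.1 ± 1.93. Camera placed the TGF-β and activin response, contractile, cholesterol synthesis and peripheral neuron lists higher and the proliferation list lower (BH-adjusted p = 0.00276, 0.00896, 0.0119, 0.0239 and 0.0440). With an estimated correlation the adjusted p were 0.655, 0.640, 0.817, 0.640 and 0.831. List medians relative to all genes were 0.32, 0.26, 0.24, 0.74 and -0.18. The remaining lists tested did not pass camera in this comparison. Camera's direction was down for chondrogenic genes, whose mean was 0.01, and for pluripotent cell markers, whose median was 0.03.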

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

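The minimum change, the estimated correlation, fry and the left-out libraries were planned, and leaving out short genes was chosen after the data were seen. Of 176 calls of named genes, 152 held in each of the 9 fits that left out 1 library, and 151 in every alternative that tested them. Only 146 were tested in every alternative, and 130 of those held throughout. None reversed. Counts of changed genes stayed within 1.5 times the reported count under each alternative for FSB minus F (5536) and F_FSB minus FSB (5527), except with a minimum log2 change of 1, which keeps fewer genes by construction (1533 and 1510). Leaving out a library gave 3880 to 5764 genes for FSB minus F and 4070 to 5429 for F_FSB minus FSB. For F_FSB minus F, left-out libraries gave 0 to 77 genes, the highest without F replicate 1. No filter on low values gave 0 genes there (limma, 1596 at an unadjusted p under 0.05), with more genes tested. A fit of only the 2 groups compared gave 1 gene, and it was not GAS1. The share of calls that turned over on withdrawal (80.5%) ran from 68.8% without F_FSB replicate 3 to 87.2% without F replicate 3. Camera passed 17 list tests, 13 to 20 with a library left out, and 0 with an estimated correlation (57 tests). Fry passed 18. It turned the endothelial list up in FSB minus F (adjusted p = 0.00939) and down in F_FSB minus FSB (adjusted p = 0.00199). Fry does not compare a list with other genes, and that list has members of both directions. The cause was not tested further. Over all values and alternatives, 7008 kept their direction and side of the threshold, 186 lost the threshold and 59 gained it. A further 85 were counts that moved by over 1.5 times or values without a call that changed sign.

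The data gave no steady sign that culture numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.136 to 0.292, and 3 of 9 libraries correlated best with their own number. The 0.292 was for F replicate 1 with F_FSB replicate 1. The highest value between different numbers was 0.127, for F replicate 2 with F_FSB replicate 3. With the number as a replicate block, limma gave 4842, 4983 and 0 genes for FSB minus F, F_FSB minus FSB and F_FSB minus F, with 1052 at an unadjusted p under 0.05 in the last. Unknown fragment counts and the lower estimated depth of F_FSB replicate 2 limit what can be said of low genes.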

Other observations

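The POU5F1, NGFR and matrix share tests were chosen after the result was seen, as were the genes named in this part and the limit of 25% below. The let-7 and aryl hydrocarbon receptor lists were written after the rise of LIN28A and CYP1A1 was seen and before the lists were tested. Leaving aside microRNA and small nucleolar RNA genes, 1521 genes changed by at least 1 on the log2 scale between FSB and F. Of these, 38 went under 25% of the way from the FSB level to the F level on withdrawal, 25 of them lower and 13 higher in FSB. That number depended on single libraries. It was 112 without F replicate 1, 22 without F replicate 3, 17 without FSB replicate 1 or 2, 25 without FSB replicate 3 and 71 without F_FSB replicate 3. Lower genes included BOC, which like GAS1 encodes a surface protein that binds Hedgehog ligands, at 65.8 ± 42.0 FPKM in F, 10.8 ± 1.34 in FSB and 11.2 ± 3.42 in F_FSB (SD, n = 3). The transcription factors TBX15 (7.85 ± 3.48, 2.63 ± 0.0422 and 2.84 ± 0.477 FPKM), MEIS1 (5.02 ± 4.13, 0.468 ± 0.339 and 0.847 ± 0.301) and SIM2 (2.72 ± 0.894, 0.328 ± 0.0796 and 0.415 ± 0.191) were also near their FSB level in F_FSB. In F replicate 1, BOC (17.5 FPKM, against 85.5 and 94.3) and TBX15 (3.84, against 9.67 and 10.0) lay nearer the FSB level than in F replicates 2 and 3. BOC left the set of changed genes without F replicate 2, F replicate 3 or FSB replicate 2, and TBX15 did so without F replicate 3. MEIS1 returned by 25% or more without F replicate 2 or F_FSB replicate 2. SIM2 stayed under 25% in each of the 9 fits. Of these 38 genes GAS1 alone passed between F_FSB and F.

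LIN28A rose in FSB with LIN28B and TRIM71, which encode other RNA-binding proteins of stem cells. Undifferentiated stem cells are argued against, because mean POU5F1 in FSB was 0.0817% of mean LIN28A. As a list, genes held down by let-7 rose together with LIN28A. Of 21 let-7 targets listed from background knowledge, 15 rose, 1 fell and 5 did not pass between FSB and F. Their median log2 change was 1.33, not relative to all genes (camera with an estimated correlation, p = 0.0359, unadjusted for 2 lists in 3 comparisons). Because LIN28A blocks let-7 maturation, such a rise can follow from high LIN28A. It cannot tell whether relief of let-7 repression was a cause or a consequence. ARID3B went from 1.25 ± 0.257 to 19.3 ± 3.81 FPKM and CCND2 from 4.49 ± 2.35 to 64.1 ± 4.91, while HMGA2, a classic target, fell from 211 ± 63.6 to 113 ± 14.3. MicroRNA levels were not analysed here, and the cause of the rise in LIN28A stays open.

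The rise of CYP1A1 in FSB might reflect activation of the aryl hydrocarbon receptor, of which it is a textbook target. Of 7 other targets tested 3 rose and 2 fell, and the list gave p = 0.711 (camera with an estimated correlation, unadjusted), so the list leaves this open. NQO1 went from 66.7 ± 17.4 to 793 ± 61.9 FPKM and the amino acid transporter SLC7A5 from 2.90 ± 0.879 to 32.5 ± 10.2, while CYP1B1 went from 33.8 ± 10.5 to 8.78 ± 0.449 FPKM. The targets AHRR and TIPARP did not pass (limma, BH-adjusted p = 0.646 and 0.866). AHRR had 5.27 ± 1.93 FPKM in F and 5.83 ± 1.17 in FSB, and TIPARP 12.1 ± 13.2 and 9.77 ± 2.34.

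Calls higher in FSB outnumbered lower ones with the deposited values. The test written first, the 49.5% of calls higher with scaling by median ratios, decides nothing, because that scaling centres the changes, and the matrix share test replaced it. A few abundant transcripts could shift all others. By its approximate share, the matrix list alone would shift other genes by 0.0897 on the log2 scale, against the median of 0.14 observed. That is part of the shift, so a composition effect and a general change in expression cannot be told apart by this value.

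NGFR was uneven among the F libraries. FSB-like cells left in F replicates 2 and 3 could be a source. Among 93 other genes at least 8-fold higher in FSB than in F_FSB, the median share of the FSB level in F replicate 2 above F replicate 1 was -0.121%, against 33.9% for NGFR, which argues against it. For F replicate 3 it was 0%, against 14.4%. What set NGFR in these cultures stays open.

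With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5536 genes for FSB against F and the highest other 3, and 5527 for F_FSB against FSB and the highest other 4, with 1 of 10 splits as large in each. For F_FSB against F, the real split gave 1 gene and 3 of 10 splits gave as many. The highest other gave 118, with F replicate 1 and F_FSB replicates 1 and 2 against the rest. What these libraries share was not tested.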
